A study of Homo sapiens with 6 samples.

How the data were processed

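RNA was sequenced from SW620 cells, an established human colorectal cancer line, that carried lentiviral shRNA constructs under puromycin selection. Per the submitters' protocols, libraries were made with a stranded poly(A) kit and sequenced as paired ends on an Illumina instrument. The deposited table holds a whole-number read count for each of 19672 genes in each of 6 libraries, and the counts are not scaled between libraries, per the file headers and the values. Per the submitters' processing notes, the tools were Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b and DESeq2, with genome build hg38. Their order and the version of DESeq2 are not given in the sources used here, and neither is how reads were assigned to genes, including those of overlapping genes, near-identical copies and the opposite strand. StringTie estimates the abundance of transcripts, so the whole numbers may be sums of such estimates in place of tallies of reads, and the tests used here take them as tallies. Of the genes listed, 19505 were matched to the RefSeq annotation of GRCh38.p14, which gave the positions printed, and 13253 of the genes tested had a position.

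Libraries were grouped by their titles into scramble, C3 and C6, with 2 libraries each. The design text speaks of a pair of shRNAs against DKC1, but which of them C3 and C6 carry is not given in the sources used here. The genotype tag of 1 C3 library reads control, and its group was taken from its title. CPM values, counts scaled to a common library size, were computed from the library sizes scaled by TMM. Means are given with the SD of 2 libraries and log2 fold changes with standard errors of the fit.

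The main test was the quasi-likelihood test of edgeR 4.0.16 (robust, TMM scaling, filterByExpr) in R 4.3.3, which kept 13299 genes. All 6 libraries were fitted as 3 groups with 3 residual degrees of freedom. Contrasts compared C3 with scramble, C6 with scramble, the mean of both lines with scramble, and C6 with C3. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Genes called with the same sign in C3 and C6 were counted, and the count was set beside that of independent lists and beside 20 simulations of unchanged groups that share the scramble libraries.

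Of 41 gene lists, 40 had at least 5 tested members; the list of small nucleolar RNA host genes had fewer and was left out. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2, and their p-values were adjusted by Benjamini-Hochberg over the 40 lists. The same test was run with a correlation estimated for each list, which limits it to the 3 residual degrees of freedom. Fry was run as a test of whether a list's genes move, on balance, one way. The groups, the tests, the lists, the rule for naming genes and all alternatives except those said to come later were chosen before the data were examined. The comparison of lists between C6 and C3 and the removal of the positional shift were chosen after seeing the data.

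Genes were named by a rule. DKC1 was always named, and so were the 12 genes with the largest rise and the 12 with the largest fall in the mean comparison. These had to be called there and, with the same sign, in both lines, to have at least 5 CPM on average over the libraries, and to have all 4 knockdown libraries on the same side of both scramble libraries. Genes with LOC, clone-type or antisense names were not taken. For C6 against C3, and for genes called with opposite signs, the 6 largest in each direction were named. From each list up to 4 members with the smallest p in the mean comparison were named, and any member of the sphingolipid lists could be. After the rule was applied, 4 of the genes it named were left out without replacement and are not reported here.

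Positional blocks were searched with the running median of 51 neighbouring genes. A block was a run of at least 20 genes, with gaps of up to 10, beyond the 95th percentile of the highest values of 100 random gene orders. The positional shift was removed by entering the running median of each knockdown line as an offset for the libraries of that line.

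The fitting steps were tested on simulated data in which known genes were changed by known fold changes. In 5 simulations over 13090 genes with gene-specific dispersion, the mean comparison recovered 38.8% of genes changed 1.25-fold, 74.8% of those changed 1.5-fold, 81.6% of those changed 2-fold and 96.3% of those changed 4-fold. In those simulations 11.2% of its calls were false, above the threshold of 5%, against 4.44% when dispersion followed the trend. Few genes were changed there, by the same amount in both lines, so this share is not an estimate for the calls made here. Counts of called genes are still to be read with a share of false calls that can exceed the threshold.

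The alternatives tried were median-of-ratios (RLE) and upper-quartile scaling, no low-count filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit of only the groups compared, leaving out each library in turn, and the removal of the positional shift. No comparison of other sample splits was made, because groups hold 2 libraries. Figures were drawn with matplotlib 3.10.9. DNA copy number was not analysed here.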

Results

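Messenger RNA was measured in SW620, a human colorectal cancer cell line, after stable lentiviral knockdown of DKC1. DKC1 encodes dyskerin, the pseudouridine synthase of the H/ACA ribonucleoproteins and a component of telomerase. The 6 libraries fell into 3 groups of 2: cells carrying a scrambled shRNA, and 2 DKC1 knockdown lines called C3 and C6. The total count per library was 26392238 and 26077966 for scramble, 31021000 and 28283524 for C3, and 26889511 and 28425155 for C6. At these depths 3 counts correspond to between 0.0967 and 0.115 CPM (counts scaled to the library size), a floor that covers counting error only. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 7.59, 6.08 and 8.30 in scramble, C3 and C6. The titles call the 2 libraries of a group biological replicates and do not say whether they were separate cultures. P-values of the main test thus measure the spread between libraries of the same group. They do not measure the spread between the knockdown lines or between independently made scramble lines.

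DKC1 itself (GRCh38 chromosome X, 154762864 to 154777689) was lower in all 4 knockdown libraries. It stood at 317 ± 3.45 CPM in scramble (SD, n = 2), 147 ± 3.28 CPM in C3 and 68.7 ± 2.27 CPM in C6. These levels were 46.3% of scramble in C3 and 21.7% in C6. The log2 fold change was −1.11 in C3 (adjusted p = 4.3e-09) and −2.21 in C6 (adjusted p = 3.5e-12) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. C6 lay below C3 by a log2 difference of −1.10 ± 0.06 (SE). One C3 library has a genotype tag that reads control while its title names the knockdown; its DKC1 level of 144 CPM lay beside the 149 CPM of the other C3 library, and it was kept in C3 as its title gives.

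**Figure D1:**
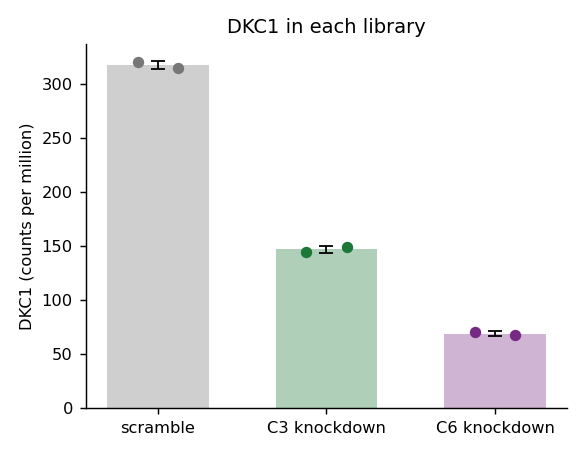
DKC1 in CPM in each of the 6 libraries (points) with the mean of each group and its SD (n = 2). Both C3 libraries lie below both scramble libraries, and both C6 libraries lie below both C3 libraries.

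The first comparison asked what changed in the mean of both knockdown lines against scramble. Among the 683 higher genes that met the rule for naming, the largest rise was that of IGFBP1, a secreted binding protein of insulin-like growth factors. It went from 4.15 ± 0.703 CPM in scramble to 10.4 ± 0.761 in C3 and 27.2 ± 1.84 in C6 (SD, n = 2). Its mean log2 fold change was 2.02 ± 0.13 (SE). EEF1A2, a translation elongation factor, rose from 33.1 to 52.9 and 285 CPM (1.89 ± 0.06). CHN2, a Rac GTPase-activating protein, rose by 1.72, and TNFRSF19, a receptor of the tumour necrosis factor receptor family and a WNT target, by 1.70. MALL, a membrane raft protein, rose from 6.34 to 11.3 and 36.3 CPM (1.68). RARRES2, which encodes the chemoattractant chemerin, rose by 1.65, FILIP1L by 1.57, the zinc finger factor ZBTB46 by 1.55 and ROR1, a receptor of WNT5A, by 1.51. BEAN1 rose by 1.47, the protease inhibitor SERPINA1 from 13.0 to 27.9 and 40.1 CPM (1.37), and the acetylcholine receptor subunit CHRNA1 by 1.34.

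The falls were larger. SBSPON, a thrombospondin-domain matrix protein, fell from 20.5 ± 0.165 CPM in scramble to 1.98 ± 0.471 in C3 and 0.742 ± 0.185 in C6, a mean log2 fold change of −4.08 ± 0.16 or 16.9-fold. XK, the membrane protein that carries the Kx blood group antigen, changed by −3.69, and RAMP1, a partner of the calcitonin receptor family, by −3.18. WNT11, a ligand of non-canonical WNT signalling, fell from 26.7 to 9.24 and 1.5 CPM (−2.84). BCHE, which encodes butyrylcholinesterase, changed by −2.71, the tight junction protein MARVELD3 by −2.58, the sodium channel SCN9A by −2.42 and C6orf15 by −2.37. ARHGEF38, a guanine nucleotide exchange factor, changed by −2.26 and GASK1B by −2.22. SGPP2, a phosphatase of sphingosine 1-phosphate, fell from 13.2 ± 0.978 CPM to 3.31 ± 0.156 in C3 and 2.69 ± 0.496 in C6 (−2.14 ± 0.14). ITGB7, an integrin beta subunit, changed by −2.10, from 19.4 CPM to 1.65 in C3 and 12.3 in C6. All 4 knockdown libraries lay on the same side of both scramble libraries for each of these 24 genes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the mean comparison gave an adjusted p of 2.6e-08 for IGFBP1, 1.2e-10 for SBSPON and 4.1e-08 for SGPP2. Of the 24 genes, 8 lie in a chromosome block, described further on, whose genes shifted together in C3 or C6. EEF1A2, ZBTB46, CHN2, RARRES2, GASK1B, SCN9A and SGPP2 moved in the direction of their block, and CHRNA1 moved against it. CHN2, FILIP1L, ZBTB46 and ITGB7 also overlap another gene, whose reads could be shared with theirs.

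Across the 13299 genes tested, 4382 passed an adjusted p of 0.05 in the mean of both lines, 2212 higher and 2170 lower. Of these, 126 were at least 2-fold higher and 479 at least 2-fold lower. With upper-quartile scaling the share of calls that were higher went from 50.5% to 37.2%. C3 alone gave 3230 calls (1654 higher and 1576 lower) and C6 alone 6205 (3168 higher and 3037 lower). In C3 the share of higher calls went from 51.2% to 41.7% with upper-quartile scaling, and in C6 from 51.1% to 41.6%. When the 4 knockdown libraries were treated as 1 group against scramble, which counts the difference between the lines as spread, 80 genes passed and DKC1 did not (log2 fold change −1.56, adjusted p = 0.124 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without scramble replicate 2 the mean comparison gave 2444 calls.

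Both lines shared 1335 genes called in the same direction, 724 higher and 611 lower, among them IGFBP1, SBSPON and SGPP2. Independent lists of these sizes would share 394 higher and 359.9 lower genes. A further 656 genes were called in opposite directions, against 753 for independent lists, 349 of them lower in C3 and higher in C6. The fold changes of the lines had a covariance of 0.228 across genes, against 0.0355 in 20 simulations of unchanged groups set against the same controls, a difference of 0.192. Their correlation across genes, which are not independent replicates, was 0.32, against 0.48 in the simulations, and 57.3% of genes had the same sign, against 66.8%. The simulations had on average 0.85 genes called in both lines with the same sign, at most 5, and 0.1 with opposite signs, at most 1. No gene was changed in them, and C3 and C6 had only 4.55 and 4.5 calls there on average. Few shared calls follow from that setting, so they cannot say how many of the 1335 come from the shared controls. The 2 scramble libraries were not split between the lines, so part of the excess may come from the shared controls. Without scramble replicate 2 the genes shared in direction numbered 779, and without C3 replicate 2 they numbered 856.

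**Figure D2:**
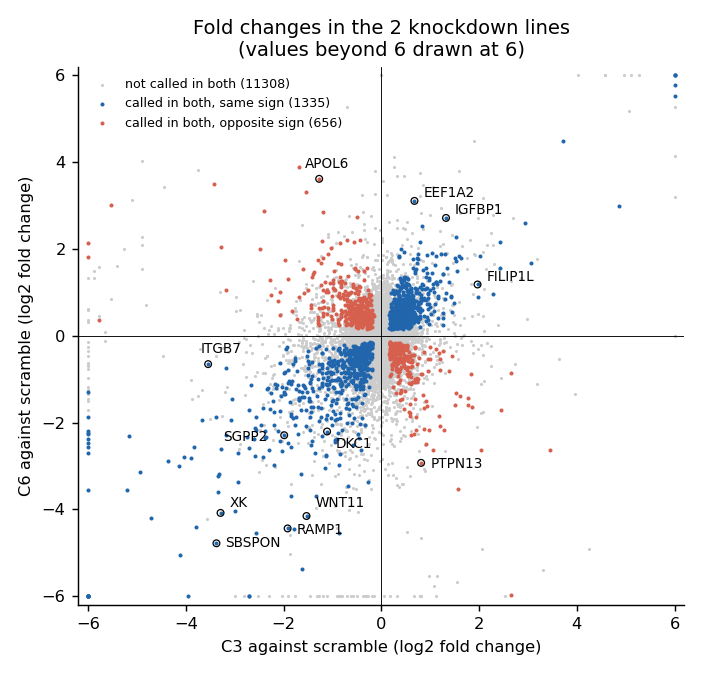
Log2 fold change against scramble in C3 (horizontal) and C6 (vertical) for each gene tested, with values beyond 6 drawn at 6. Coloured points mark the 1335 genes called in the same direction in both lines and the 656 called in opposite directions.

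Gene groups fixed in advance were tested with camera. In the mean of both lines 11 of 40 lists were called, and none held when camera estimated the correlation within each list, where the smallest adjusted p was 0.18. That version of camera rests on the 3 residual degrees of freedom of the fit. Whether it could call a list on so few was not tested, so its values alone do not decide whether a list moved. That limit is the same for every list. The nuclear respiratory chain list still had a higher adjusted p there (0.637) than apoptosis regulators (0.509), a list not called at the preset correlation. For the respiratory chain the call thus also rests on the low preset correlation. Cholesterol synthesis, mitochondrially encoded and immediate-early genes were also called in each line on its own. The nuclear respiratory chain, NRF2, lysosome, ATF4, mesenchymal and epithelial lists were called in C3 and not in C6, G2/M genes in C6 and not in C3, and p53 targets in neither line. Of these lists, the respiratory chain, epithelial and G2/M lists also differed between C6 and C3 at the preset correlation. In the direction of each list, fewer genes were called in both lines than in the mean. In both lines 17 respiratory chain, 11 immediate-early, 6 lysosome, 6 ATF4, 6 mesenchymal, 5 NRF2, 3 mitochondrially encoded and 3 p53 target genes rose. Likewise 5 epithelial and 2 G2/M genes fell in both. Against their list, 1 immediate-early, 1 lysosome and 1 p53 target gene fell in both lines and 1 epithelial gene rose. With the shift of neighbouring genes removed, the respiratory chain (adjusted p = 0.0262) and lysosome lists (0.0209) were called in C6 too, and p53 targets in C3 (0.0407). Counts of single genes in the lists depend on the setting: of 923 list genes 235 rose and 164 fell in the mean, against 181 and 199 with upper-quartile scaling, 136 and 115 without scramble replicate 2, 187 and 113 without scramble replicate 1, and 7 and 2 with the knockdown libraries as 1 group. Cholesterol synthesis genes fell together: of 25 measured, 20 fell, 2 rose and the median log2 fold change was −0.44 (camera adjusted p = 3.0e-07; adjusted p = 0.18 with an estimated correlation). Adjusted over the list alone the counts were 21 and 2, and 15 fell in both lines. DHCR7, the last enzyme of the Kandutsch-Russell route to cholesterol, fell from 167 CPM in scramble to 104 in C3 and 77.1 in C6 (−0.90). The sterol methyl oxidase MSMO1 changed by −1.18, in a block of chromosome 4, and the sterol carrier STARD4 by −1.10. Among fatty acid synthesis genes 7 of 17 fell and 1 rose, as they did adjusted over the list alone, which was not called (adjusted p = 0.0555). SCD, the stearoyl-CoA desaturase, fell from 637 to 435 and 443 CPM (−0.54), FASN changed by −0.56 and the acyl-CoA ligase ACSL3 by −0.60, while the acetyl-CoA synthetase ACSS2 rose by 1.00.

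Nuclear genes of the respiratory chain were higher as a list, with 32 of 58 higher and 3 lower (37 and 3 adjusted over the list alone) and a median of 0.22 (adjusted p = 1.2e-06; adjusted p = 0.637 with an estimated correlation). Examples are ATP5MC1, a subunit of ATP synthase (0.64), NDUFB8 of complex I (0.46), UQCRQ of complex III (0.44) and COX8A of complex IV (0.43). Of 13 mitochondrially encoded genes 7 rose and none, 0, fell (8 and 0 adjusted over the list alone), with COX3 at 0.36 and ATP8 at 0.32 (median 0.20, adjusted p = 0.00165; adjusted p = 0.509 with an estimated correlation). The mitochondrial share of counts was 5.92% and 6.02% in scramble, 6.49% and 6.39% in C3, and 6.63% and 6.87% in C6. NRF2 targets and ferroptosis defence genes were also higher, 13 of 26 against 2 lower, the same counts adjusted over the list alone (median 0.19, adjusted p = 0.00107; adjusted p = 0.414 with an estimated correlation). They included the sulfiredoxin SRXN1 (0.55), the lipid peroxidase GPX4 (0.43) and the ferritin light chain FTL (0.40). Lysosome and autophagy genes rose in 13 of 33 cases and fell in 4, also adjusted over the list alone (median 0.14, adjusted p = 0.0103; adjusted p = 0.509 with an estimated correlation). The protective protein CTSA rose by 0.83 and the cathepsin CTSZ by 0.55, both in the block on chromosome 20, and the autophagy kinase ULK1 by 0.46. With the shift of neighbouring genes removed CTSZ stood at 0.08 and was not called. The lysosome list lost its call without scramble replicate 2 (adjusted p = 0.0506).

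Immediate-early genes rose in 15 of 25 cases and fell in 1 (16 and 1 adjusted over the list alone), with a median of 0.37 (adjusted p = 1.1e-06; adjusted p = 0.18 with an estimated correlation). KLF6 rose from 79.9 ± 4.37 CPM to 124 ± 5.14 in C3 and 236 ± 1.20 in C6 (1.10 ± 0.06), JUN from 140 to 226 and 302 CPM (0.90), EGR3 by 0.93 and JUNB by 0.61. Genes of the ATF4 and integrated stress response rose in 14 of 31 cases and fell in 3 (17 and 3 adjusted over the list alone; median 0.15, adjusted p = 0.0103; adjusted p = 0.509 with an estimated correlation). SESN2, a stress-induced sestrin, rose by 0.55 and the transcription factors CEBPB and ATF3 by 0.54 and 0.51. CEBPB lies in the block on chromosome 20 and stood at 0.12, not called, once the shift of neighbouring genes was removed. In C6 alone 12 genes of the ATF4 list rose and 10 fell, also adjusted over the list alone (median 0.09, adjusted p = 0.765). Targets of p53 rose in 9 of 23 cases and fell in 1, also adjusted over the list alone (median 0.16, adjusted p = 0.0103; adjusted p = 0.414 with an estimated correlation). The antiproliferative gene BTG2 rose by 0.83, and the cyclin G1 gene CCNG1, a p53 target too, changed by −0.72.

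G2/M genes fell in 20 of 45 cases and rose in 5 (23 and 8 adjusted over the list alone), with a median of −0.18 (adjusted p = 0.00418; adjusted p = 0.414 with an estimated correlation). The spindle protein TACC3 changed by −0.61 and the chromatin protein HMGB2 by −0.47, both in blocks of chromosome 4, the mitotic kinase PLK1 by −0.37 and the kinesin KIF20B by −0.35. HMGB2 turned to 0.054, not called, once the shift of neighbouring genes was removed. In C3 alone 4 G2/M genes rose and 3 fell, also adjusted over the list alone (median −0.02, adjusted p = 0.883). Epithelial markers fell in 12 of 25 cases and rose in 4, also adjusted over the list alone (median −0.23, adjusted p = 0.0465; adjusted p = 0.509 with an estimated correlation). Their call was lost with a filter of 1 CPM in 2 libraries (adjusted p = 0.051) and with the replicate number as a block (0.0616). It was also lost without scramble replicate 1 (0.0501), scramble replicate 2 (0.0901), C3 replicate 1 (0.0917) or C6 replicate 1 (0.0582). In C6 alone 7 epithelial markers rose and 7 fell, also adjusted over the list alone (median −0.01, adjusted p = 0.953). The membrane protease ST14 changed by −1.97, E-cadherin (CDH1) by −1.13 and the splicing regulator ESRP1 by −1.04, while the claudin CLDN4 rose by 0.82. Mesenchymal markers rose in 9 of 17 cases and fell in 2 (10 and 2 adjusted over the list alone; median 0.32, adjusted p = 0.0101; adjusted p = 0.569 with an estimated correlation). Among them the transcription factor SNAI2 rose by 0.74. The mesenchymal list was not called in C6 alone (adjusted p = 0.0907), and without scramble replicate 1 its call was lost in the mean (0.239). No called list changed the sign of its median under either other scaling. With upper-quartile scaling the medians of called lists shrank by over 1.5 times for cytosolic ribosomal proteins in C6 (0.11 to 0.05), lysosome genes in the mean (0.14 to 0.09) and ribosome biogenesis in C3 (0.09 to 0.06).

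**Figure D3:**
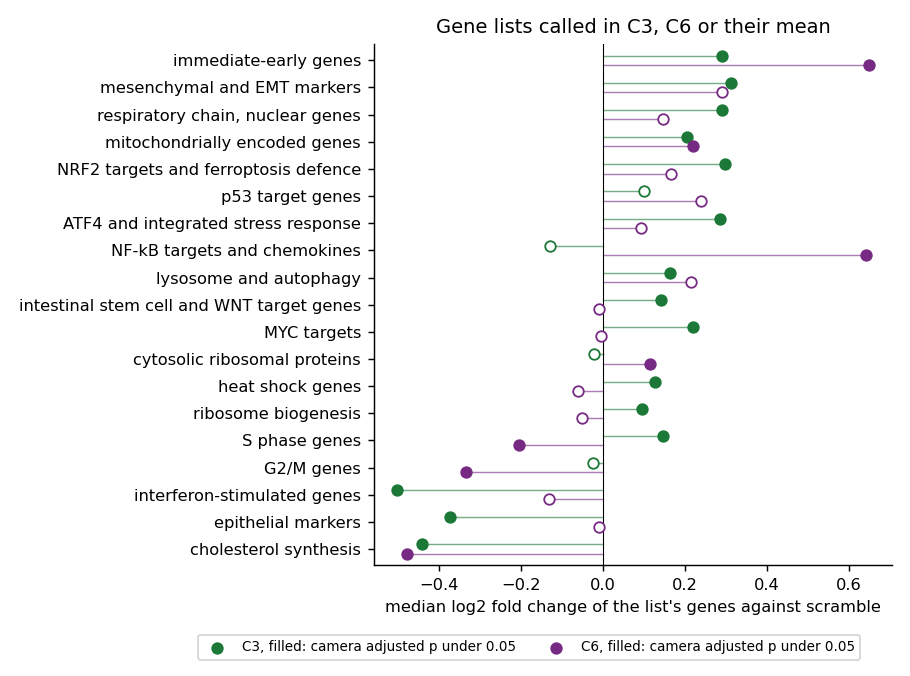
Median log2 fold change against scramble of each gene list called in C3, C6 or their mean, with filled markers where camera called the list at the preset correlation. Cholesterol synthesis lies near −0.44 in C3 and −0.48 in C6, and the immediate-early list is at 0.29 in C3 and 0.65 in C6.

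Sphingolipid genes were examined because the title of the series names sphingolipid biosynthesis. In 5 lists 84 genes were tested, of which 35 changed in the mean of both lines, 18 higher and 17 lower. Of all genes tested 33% were called in that comparison. With upper-quartile scaling 14 were higher and 21 lower, and 4 of the 35 lost their call (TECR, SMPD1, PLEKHA8 and SPNS2). In both lines alike, 4 rose (GAL3ST1, B4GALT5, ST3GAL2 and B3GNT5) and 5 fell (SPTLC2, ELOVL7, SGPP2, ST6GALNAC5 and SUMF1). These 9 of 84 lie near the share over all genes, 1335 of 13299. None of the 5 lists was called by camera. In de novo ceramide synthesis 8 of 21 genes fell and 4 rose (10 and 4 adjusted over the list alone; adjusted p = 0.453). SPTLC2, a subunit of the serine palmitoyltransferase that starts the pathway, fell from 75.7 ± 4.60 CPM to 63.7 ± 1.73 in C3 and 44.4 ± 1.41 in C6 (−0.51 ± 0.06). The ceramide synthase CERS6, in a block of chromosome 2 in C6, changed by −0.32, with −0.02 in C3, and the fatty acid elongase ELOVL7 by −1.01. The elongase ELOVL1 rose by 0.35 in the mean, with 0.86 in C6 and −0.17, not called, in C3. The ceramide synthase CERS2 rose by 0.20.

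Of 13 genes of sphingomyelin synthesis and turnover 4 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.326). The ceramide kinase CERK rose by 0.38, with 0.75 in C3 and 0.0008, not called, in C6, and the sphingomyelin synthase SGMS2 by 0.33. The phosphodiesterase SMPDL3B changed by −0.77, with −0.17, not called, in C3 and −1.36 in C6. Of 18 ceramidase and sphingosine 1-phosphate genes 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.82). SGPL1, the sphingosine 1-phosphate lyase, stood at 150 ± 1.04 CPM in scramble, 153 ± 3.26 in C3 and 290 ± 25.5 in C6 (0.49). In glycosphingolipid synthesis 5 of 18 genes rose and 4 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.945). The sulfotransferase GAL3ST1 stood at 1.24 and the glycosyltransferases B3GNT5 and B4GALT5 at 0.82 and 0.30. The fucosyltransferase FUT1 stood at −0.71, with 0.09, not called, in C3 and −1.51 in C6. Among 14 genes of lysosomal breakdown 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.893), with the sulfatase activator SUMF1 at −0.75, GM2A at −0.61 and the galactosidase GLA at 0.28. Of the 84 genes 42 differed between C6 and C3, near the 49.2% of all genes tested. Of the 35 called genes 30 stayed called in the same direction once the shift of neighbouring genes was removed. ORMDL1 and B4GALT5 changed sign there, to 0.063 and −0.085, and CERS6 stood at −0.05, TECR at 0.05 and PLEKHA8 at 0.03, none of them called. Without scramble replicate 1, 13 of the 35 lost their call, among them CERS2, SGMS2 and SMPDL3B (adjusted p = 0.0513, 0.108 and 0.0903 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without scramble replicate 2, 14 lost it, among them SGMS2, GAL3ST1, GM2A and GLA (0.0558, 0.0783, 0.0514 and 0.169). With the 4 knockdown libraries as 1 group 34 of the 35 lost it, and SGPP2 kept it.

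**Figure D4:**
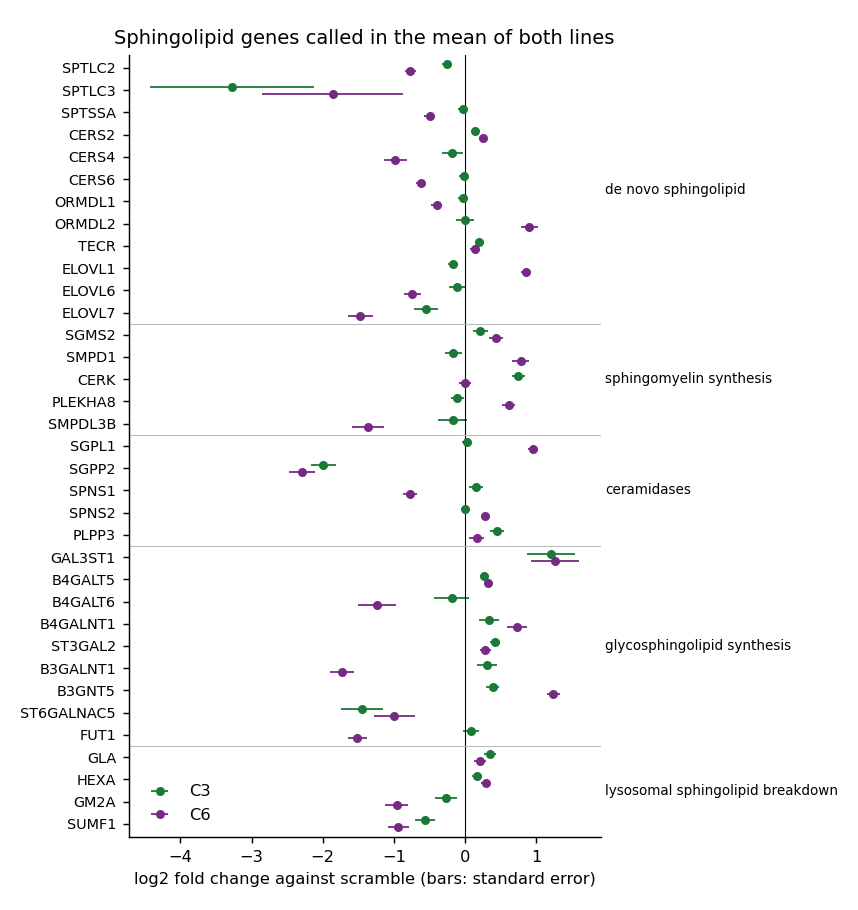
Log2 fold change against scramble in C3 and C6, with standard errors, of the 35 sphingolipid genes called in the mean of both lines. SGPP2 lies at −1.99 in C3 and −2.29 in C6, and SGPL1 at 0.03 in C3 and 0.95 in C6.

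No list of the partners of DKC1 was called in the mean, in C3, in C6 or between the lines, before the shift of neighbouring genes was removed. Values here are for the mean unless a line is named. Of 10 genes of the H/ACA ribonucleoprotein and its assembly 2 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.742). The assembly factor NAF1 changed by −0.61, in the block of chromosome 4, and the core proteins NHP2 and GAR1 by 0.23 and 0.30, while NOP10 stood at 0.14 and was not called. In C3 alone 2 genes of this list rose and 1 fell, and in C6 alone 0 rose and 1 fell, both also adjusted over the list alone. No rise in this list was thus called in C6, the line with less DKC1. The call of GAR1 was lost with upper-quartile scaling (adjusted p = 0.0899 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with DESeq2 (0.104), with limma-voom (0.0722) and with the replicate number as a block (0.0503). It was also lost without scramble replicate 1 (0.16), scramble replicate 2 (0.207), C3 replicate 2 (0.163) or C6 replicate 1 (0.126), and that of NHP2 without scramble replicate 2 (0.182). NAF1 stood at −0.15, not called, once the shift of neighbouring genes was removed. Telomerase and shelterin genes rose in 2 and fell in 1 of 14 cases, also adjusted over the list alone (adjusted p = 0.534), with the telomere repeat binding factor TERF1 at −0.33. The calls of the shelterin genes that rose, ACD and TINF2, were both lost with upper-quartile scaling (adjusted p = 0.0566 and 0.061 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), without scramble replicate 2 (0.192 and 0.104) and without C3 replicate 2 (0.0611 and 0.0608). That of TINF2 was also lost with DESeq2 (0.0585), without scramble replicate 1 (0.0819) and with the shift of neighbouring genes removed (0.0512). In the mean none, 0, of 12 pseudouridine synthases was called, over all genes or adjusted over the list alone (adjusted p = 0.942). In C6 alone 3 of them fell and 0 rose, also adjusted over the list alone. In C3 1 rose (0 adjusted over the list alone). With the shift of neighbouring genes removed their list was called between C6 and C3 (median −0.22, camera adjusted p = 0.0201). Of the telomerase and shelterin genes 5 rose and 1 fell in C6 alone. TERT rose there by 1.03, and stood at 0.65, not called, once that shift was removed.

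C3 was then set against scramble on its own. Epithelial markers fell as a list: 14 of 25 fell and 3 rose, also adjusted over the list alone (median −0.37, adjusted p = 0.000406; adjusted p = 0.301 with an estimated correlation). ST14 fell from 121 ± 2.67 to 13.3 ± 0.115 CPM (−3.18), CDH1 from 225 ± 7.02 to 58.1 ± 3.17 CPM (−1.96) and ESRP1 from 175 ± 2.65 to 62.1 ± 0.377 CPM. Interferon-stimulated genes fell in 11 of 32 cases and rose in 2 (14 and 2 adjusted over the list alone; median −0.50, adjusted p = 0.000406; adjusted p = 0.273 with an estimated correlation). The antiviral membrane protein IFITM3 changed by −1.20 and the deISGylase USP18 by −0.65. Of antigen presentation genes, a list that was not called (adjusted p = 0.0546), the class I transactivator NLRC5 changed by −2.26, HLA-B, which has near-identical relatives, by −1.26 and the immunoproteasome subunit PSMB8 by −1.16. Cholesterol synthesis genes fell in 18 cases and rose in 0 (19 and 1 adjusted over the list alone; median −0.44, adjusted p = 9.0e-07; adjusted p = 0.273 with an estimated correlation).

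On the rising side, 40 of 58 respiratory chain genes rose in C3 and 0 fell (49 and 0 adjusted over the list alone; median 0.29, adjusted p = 1.0e-11; adjusted p = 0.46 with an estimated correlation), among them ATP5MC1 at 0.58 and NDUFB8 at 0.57. Mitochondrially encoded genes rose in 6 cases, also adjusted over the list alone (adjusted p = 0.00264; adjusted p = 0.362 with an estimated correlation). ATF4 and integrated stress response genes rose in 15 of 31 cases (20 adjusted over the list alone; median 0.29, adjusted p = 1.5e-06; adjusted p = 0.273 with an estimated correlation), with the stress cytokine GDF15 at 1.12. NRF2 targets rose in 15 and fell in 1 of 26 cases (17 and 1 adjusted over the list alone; adjusted p = 1.8e-05; adjusted p = 0.273 with an estimated correlation), with FTL at 0.59 and the thioredoxin reductase TXNRD1 at 0.57. S phase genes rose in 16 of 35 cases and fell in 1, also adjusted over the list alone (median 0.15, adjusted p = 0.000406; adjusted p = 0.301 with an estimated correlation), with the replicative helicase subunit MCM5 at 0.59 and PCNA, the replication clamp, at 0.35. MYC targets rose in 11 of 21 cases, also adjusted over the list alone (median 0.22, adjusted p = 0.000453; adjusted p = 0.298 with an estimated correlation), with LDHA at 0.54 and NME1 at 0.47. Ribosome biogenesis genes rose in 7 of 52 cases, also adjusted over the list alone (adjusted p = 0.00206; adjusted p = 0.362 with an estimated correlation), with the ribosome assembly factor EIF6 at 0.32, which stood at 0.14 and was not called once the shift of neighbouring genes was removed.

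The remaining lists called in C3 were also higher. Immediate-early genes rose in 12 and fell in 3 cases (13 and 4 adjusted over the list alone; adjusted p = 0.00716; adjusted p = 0.298 with an estimated correlation), with JUN at 0.69 and KLF6 at 0.64. Mesenchymal markers rose in 7 and fell in 1, also adjusted over the list alone (adjusted p = 0.00892; adjusted p = 0.478 with an estimated correlation), with the matrix protein THBS1 at 2.03 and SNAI2 at 0.61. Heat shock genes rose in 7 and fell in 1 of 16 cases, also adjusted over the list alone (adjusted p = 0.0177; adjusted p = 0.504 with an estimated correlation), with the small heat shock protein HSPB1 at 0.61. The mesenchymal list lost this call without scramble replicate 1 (0.11), and the heat shock list without scramble replicate 1 (0.0733) or C3 replicate 2 (0.168). Lysosome and autophagy genes rose in 9 and fell in 4 (13 and 4 adjusted over the list alone; adjusted p = 0.0187; adjusted p = 0.362 with an estimated correlation). Stem cell and WNT target genes rose in 9 and fell in 3 of 24 cases (10 and 3 adjusted over the list alone; adjusted p = 0.022; adjusted p = 0.301 with an estimated correlation), with AXIN2, a feedback target of WNT signalling, at 0.60 and TNFRSF19 at 1.58. Without scramble replicate 2 the calls of the lysosome list (0.079) and of the WNT target list (0.0827) were lost. Without scramble replicate 2 C3 gave 1946 calls, and without C3 replicate 2 it gave 1947.

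In C6, the line with less DKC1, proliferation genes were lower. G2/M genes fell in 28 of 45 cases and rose in 3 (30 and 4 adjusted over the list alone; median −0.33, adjusted p = 0.000562; adjusted p = 0.37 with an estimated correlation), with TACC3 at −1.08, PLK1 at −0.88 and KIF20B at −0.60. S phase genes fell in 19 of 35 cases and rose in 5 (20 and 6 adjusted over the list alone; median −0.21, adjusted p = 0.0219; adjusted p = 0.676 with an estimated correlation), with the licensing factor CDT1, in a block of chromosome 16, at −0.74 and cyclin E2 (CCNE2) at −0.95. With the shift of neighbouring genes removed CDT1 stood at −0.11 in C6 and was not called. Cholesterol synthesis genes fell in 19 of 25 cases and rose in 3 (20 and 3 adjusted over the list alone; median −0.48, adjusted p = 4.5e-05; adjusted p = 0.267 with an estimated correlation), with STARD4 at −1.61 and DHCR7 at −1.11. Immediate-early genes rose in 19 cases and fell in 2, also adjusted over the list alone (median 0.65, adjusted p = 3.1e-06; adjusted p = 0.267 with an estimated correlation), with KLF6 at 1.56, EGR3 at 1.33 and JUN at 1.11. NF-kB targets and chemokines rose in 13 of 22 cases and fell in 2, also adjusted over the list alone (median 0.64, adjusted p = 0.011; adjusted p = 0.37 with an estimated correlation), with the chemokines CXCL8 at 1.77 and CCL20 at 1.53, while TNFAIP2 changed by −1.21.

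Cytosolic ribosomal protein genes rose in 25 of 79 cases in C6 and fell in 6 (23 and 4 adjusted over the list alone; median 0.11, adjusted p = 0.0474; adjusted p = 0.957 with an estimated correlation). That call was lost under the median-of-ratios scaling (adjusted p = 0.052), with a filter of 1 CPM in 2 libraries (0.0738) and with the replicate number as a block (0.0575). It was also lost without scramble replicate 2 (0.509) or C6 replicate 1 (0.287). RPS21, in the block on chromosome 20, rose by 0.82 and RPS23 by 0.52, while RPL13, in a block on chromosome 16, changed by −0.42. With the shift of neighbouring genes removed RPS21 and RPS23 were not called in the mean (0.13 and 0.11), though in C6 both kept their calls. RPL13 turned to 0.24 in C6 (adjusted p = 0.0113 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mitochondrially encoded genes rose in 7 of 13 cases, also adjusted over the list alone (adjusted p = 0.0316; adjusted p = 0.676 with an estimated correlation), a call lost with the 1 CPM filter (0.0514), without scramble replicate 1 (0.0553) and without C6 replicate 2 (0.0688). Single genes with large changes in C6 included EEF1A2 at 3.11, IGFBP1 at 2.71, MALL at 2.52, CLDN4 at 1.48, BCHE at −4.55, RAMP1 at −4.44, WNT11 at −4.16 and the matricellular stem cell gene SMOC2 at −3.20.

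The lines were also compared directly, C6 against C3, and differed at 6538 genes, 3339 higher in C6 and 3199 lower. SLCO1B3, an organic anion transporter, stood at 29.3 ± 2.18 CPM in scramble, 0.538 ± 0.396 in C3 and 37.5 ± 0.141 in C6 (SD, n = 2), a log2 difference of 6.14. The apolipoprotein L family member APOL6 differed by 4.89, the natural killer receptor gene KLRC2 by 4.85, the cornified envelope gene SPRR2D by 4.04 and the orphan receptor GPR35 by 3.22. CALB1, a calcium-binding protein, had 0 counts in both C3 libraries, at least 66.3-fold lower than scramble (6.75 CPM) and at least 85.5-fold lower than C6 (8.71 CPM) against a floor of 3 counts per library.

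Lower in C6 than in C3 were the phosphatase PTPN13 (27.3, 48.0 and 3.57 CPM in scramble, C3 and C6; −3.74), BCHE (−3.68), CCSER1 (−3.46), the adhesion receptor ADGRL2 (−3.45), LHFPL6 (−3.37), NREP (−3.28) and the zinc finger factor ST18 (−3.19). Apart from CALB1, BCHE and CCSER1, each of these genes was called in opposite directions against scramble in C3 and C6. KLRC2 and SPRR2D belong to families of near-identical genes, and SLCO1B3 overlaps another gene in the table, so their levels are uncertain to that extent. Of 40 lists 11 differed between the lines at the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.34. Epithelial markers were higher in C6 than in C3 in 17 of 25 cases and lower in 2, also adjusted over the list alone (median 0.66, adjusted p = 0.000441; adjusted p = 0.34 with an estimated correlation). S phase genes were lower in C6 in 25 of 35 cases and higher in 2 (28 and 2 adjusted over the list alone; median −0.38, adjusted p = 8.5e-06; adjusted p = 0.34 with an estimated correlation).

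Changed genes were not spread evenly over the genome. Long runs of neighbouring genes shifted together, a feature noticed only after the fold changes had been computed. The running median of 51 neighbouring genes reached 0.55 in C3 and 0.76 in C6, against a highest value of 0.23 and 0.37 in 100 random gene orders. C3 held 3 such blocks with 320 genes, and C6 17 blocks with 1679 genes. On chromosome 4 (156760454 to 189963192) 62 genes had a median of −0.53 in C3 and −0.55 in C6. On chromosome 7 (135092303 to 158958698) 114 genes had a median of 0.39 in C3 and 0.57 in C6, and on chromosome 20 (45469753 to 64276226) 125 genes had 0.43 and 0.54. Blocks found in C6, with none called there in C3, included 285 genes on chromosome 2 (158171073 to 231049719; −0.46), 79 on chromosome 4 (53321 to 13484340; −0.68), 123 on chromosome 13 (46553170 to 114327322; −0.51) and 71 on chromosome 16 (81739041 to 90044960; −0.67). Block genes made up 224 of the 3223 positioned calls in C3 and 1177 of 6192 in C6. With the shift of neighbouring genes removed, 73.8% of the calls in the mean comparison were kept, DKC1 among them, and all 11 lists called there stayed called. The ERK pathway, hypoxia and heat shock lists, not called there before, were then called at the preset correlation (adjusted p = 0.0157, 0.0258 and 0.0131).

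**Figure D5:**
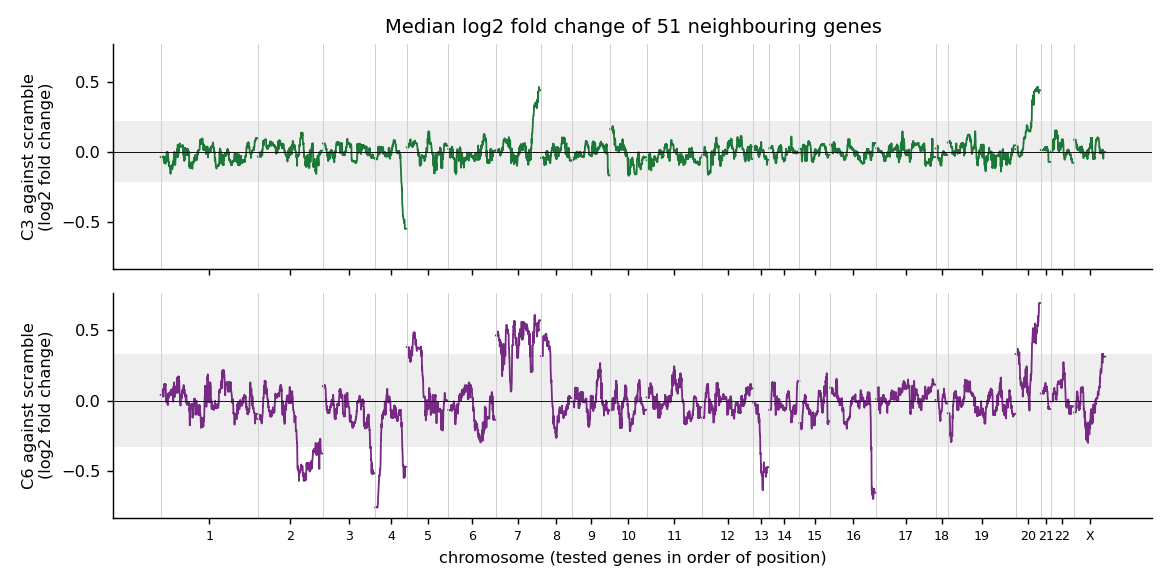
Running median log2 fold change of 51 neighbouring genes along the chromosomes in C3 and C6, with a grey band up to the 95th percentile of the highest values of 100 random gene orders. Both lines lie below the band at the end of chromosome 4 and above it at the ends of chromosomes 7 and 20.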

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

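The tests of chance clustering, of a response scaled by the depth of knockdown, of the shRNA or the history of each line and of fewer dividing cells were chosen only after the result was seen, and so were the removal of the positional shift and the list tests of C6 against C3.

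Runs of neighbouring genes shifted together, and their running median reached 0.55 in C3 and 0.76 in C6, above the highest of 100 random gene orders (0.23 and 0.37), which argues against chance clustering. After a trend on GC content and transcript length was removed, 92.9% of the median block shift remained in C6 and 101% in C3, which argues against that trend as the cause. In blocks found from every second gene, 138 of 168 left-out genes (82.1%) in C3 and 770 of 919 (83.8%) in C6 moved in the direction of the block, so a difference in DNA copy number between the lines is a candidate explanation, as a hypothesis. A regional change in transcription without a copy number change would give the same values, and no DNA data were analysed here. The blocks on chromosomes 4, 7 and 20 share their sign in C3 and C6, so it stays open whether the scramble line or the knockdown lines changed, and whether loss of DKC1 played a part was not tested.

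C3 and C6, each compared with the same scramble libraries, had 656 genes called with opposite signs. They made up 32.9% of the genes called in both lines, more than the 5% that a single response scaled by the depth of knockdown was set to allow. With the positional shift removed, 445 of the 656 (67.8%) were still called with opposite signs, so block shifts may account for part of them and not for most. With 1 line per knockdown label, an effect of the shRNA or of the history of each line cannot be told apart from a response that takes another course at a lower DKC1 level. That response is the biological explanation the design gives, and it stays untested.

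Cholesterol synthesis genes fell in C3 and in C6. With the positional shift removed at least 94.8% of the median fall was left in each line, and the medians were −0.42 in C3 and −0.59 in C6. Other scalings moved the median by at most 12.8% of its size. In C3 the values argue against a smaller share of dividing cells, since 16 of 35 S phase genes were called higher and 1 lower, also adjusted over the list alone (median 0.15, camera adjusted p = 0.000406; adjusted p = 0.301 with an estimated correlation), and the G2/M list was not called (median −0.02), but in C6 it stays open, since the S phase (−0.21) and G2/M (−0.33) lists both fell at the preset correlation. That loss of DKC1 lowers these genes is a hypothesis that remains open beside others, since there is 1 scramble line and its own history was not tested. The list was not called with an estimated correlation, and whether that test could have called it on 3 degrees of freedom was not tested.

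The direct test of C6 against C3 called 6538 genes by edgeR's quasi-likelihood test. Genes higher in C6 than in C3 by that test were CALB1, by a log2 difference of at least 6.42 against a floor of 3 counts per library, SLCO1B3 (6.14), APOL6 (4.89), KLRC2 (4.85), SPRR2D (4.04) and GPR35 (3.22). Lower in C6 were PTPN13 (−3.74), BCHE (−3.68), CCSER1 (−3.46), ADGRL2 (−3.45), LHFPL6 (−3.37), NREP (−3.28) and ST18 (−3.19). Of the 178 other genes named, 124 differed between the lines.

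By camera 11 lists differed between C6 and C3 at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.34. The median log2 difference was positive, thus higher in C6, for NF-kB targets and chemokines (0.87), epithelial markers (0.66), immediate-early genes (0.65), antigen presentation (0.37), apoptosis regulators (0.25) and cytosolic ribosomal proteins (0.13). It was negative for S phase genes (−0.38), MYC targets (−0.38), G2/M genes (−0.27), ribosome biogenesis (−0.16) and nuclear genes of the respiratory chain (−0.15). With the positional shift removed the apoptosis list was not called (median 0.17, camera adjusted p = 0.0811). Called then, though not before, were pseudouridine synthases (median −0.22, adjusted p = 0.0201), interferon-stimulated genes (0.34, 0.0359) and the ATF4 list (−0.23, 0.0439).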

How the results depend on the processing

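The removal of the positional shift was the one setting here chosen only after the result was seen; the other tests were planned. DKC1 kept its direction under every setting and its call under all but 1. With only the groups compared, where the 4 knockdown libraries form 1 group, the mean comparison gave 80 genes and DKC1 −1.56 (adjusted p = 0.124 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), since the difference between the lines then counts as spread. That setting took 158 of the named genes below the threshold. The other 48 did not change status, and they include genes called in neither fit. For genes named between C6 and C3 the setting fitted those 2 groups alone. Camera with an estimated correlation called 0 lists in the mean comparison, 0 in C3 and 0 in C6. Whether it could call a list on 3 degrees of freedom was not tested, so these losses alone do not decide whether the lists moved. That limit is the same for every list. In the mean the respiratory chain list still had a higher adjusted p there (0.637) than apoptosis regulators (0.509), which were not called at the preset correlation. Fry, another kind of test, called 24 in the mean and 23 in C6. It did not call the respiratory chain list in the mean (adjusted p = 0.067) or cytosolic ribosomal proteins in C6 (0.343), and the cause was not tested. Leaving out 1 library in turn, with its group's lone library assumed to vary like the others, gave 1946 to 3267 genes in C3, 2444 to 4041 in the mean comparison and 779 to 1190 in both lines alike. The lowest of each came without scramble replicate 2, and without C3 replicate 2 C3 gave 1947 and both lines 856. These settings kept between 54.0% and 97.0% of the calls and reversed 0. With the positional shift removed 6 named genes changed sign in the mean and none of them was called there: ORMDL1 (0.063), B4GALT5 (−0.085), RPL13 (0.045), NOP58 (0.076), HMGB2 (0.054) and PDIA4 (−0.083). In C6 alone RPL13 was called with the other sign (0.24). That setting subtracts the shift of neighbours by construction.

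Samples of the same replicate number did not deviate together (r = −0.047, 0.064 and 0.025 across genes for the pairs of groups), so the replicate number was used as a block only here. With the replicate block 2935 genes were called in C3, 5878 in C6, 4014 in the mean, 6243 between the lines and 1215 in both alike, and 89.7% of the C3 calls were kept. It called 10 lists in the mean, 15 in C3 and 6 in C6. The remaining counts stayed within 1.5 times: over RLE and upper-quartile scaling, both filters, DESeq2 and limma-voom, C3 gave 2608 to 3280 genes, C6 5287 to 6309 and the mean 3519 to 4430, the lowest by DESeq2. Depth limits genes near the floor of 0.0967 to 0.115 CPM, such as CALB1 in C3.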

Other observations

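Of the tests in this part, the search for genes at 0 in 1 replicate and the removal of the shift of neighbouring genes were chosen only after the result was seen.

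Several lists fixed in advance were not called in the mean of both lines but held genes that changed. Of all genes tested 33% were called in that comparison, so changed genes within a list do not by themselves set it apart. Outputs of the ERK pathway rose in 13 of 21 cases and fell in 3 (13 and 6 adjusted over the list alone; camera adjusted p = 0.0857), with the phosphatase DUSP4 at 0.74 and the architectural factor HMGA2 at 0.78, while the feedback inhibitors DUSP6 and SPRY2 stood at −0.60 and −0.67. Hypoxia and glycolysis genes rose in 13 of 33 cases and fell in 4 (15 and 5 adjusted over the list alone; adjusted p = 0.0509), with the enzymes ENO1 at 0.40, PGAM1 at 0.39 and PGK1 at 0.37 and the glucose transporter SLC2A1 at −0.53. Among genes of drug transport and of response to 5-fluorouracil, platinum and irinotecan, 5 of 28 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.686). The thymidine kinase TK1 rose by 0.57 and the transporter SLC22A3 by 0.76, and the efflux pump ABCC5 changed by −0.56. The DNA repair gene MGMT had 0 counts in both C3 libraries, at least 20.1-fold lower than its 2.05 CPM in scramble against a floor of 3 counts per library. Apoptosis regulators rose in 11 of 36 cases and fell in 5 (12 and 5 adjusted over the list alone; adjusted p = 0.27), with the survival factor MCL1 at 0.37 and the caspase CASP2 at 0.53, in a block of chromosome 7, which stood at 0.10 and was not called once the shift of neighbouring genes was removed.

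Interferon-stimulated genes fell in 11 of 32 cases and rose in 3 (12 and 3 adjusted over the list alone; adjusted p = 0.197), with IFITM3 at −1.09 and ISG15 at 0.73. Antigen presentation genes rose in 5 of 20 cases and fell in 6, also adjusted over the list alone (adjusted p = 0.287), and NF-kB targets rose in 5 of 22 and fell in 4, likewise also adjusted over the list alone (adjusted p = 0.197). Stem cell and WNT targets rose in 7 of 24 and fell in 3, also adjusted over the list alone (adjusted p = 0.197), and colonocyte and goblet genes rose in 5 of 17 and fell in 3, also adjusted over the list alone (adjusted p = 0.942), with HNF4A, a hepatocyte nuclear factor, at 0.43 and the goblet cell gene AGR2 at −3.42, from 3.66 CPM in scramble to 0.216 in C3 and 0.528 in C6. Endoplasmic reticulum chaperones rose in 3 of 23 and fell in 5 (adjusted p = 0.333), heat shock genes rose in 5 of 16 and fell in 1 (adjusted p = 0.142), both also adjusted over the list alone. S phase genes rose in 7 of 35 and fell in 8 (7 and 9 adjusted over the list alone; adjusted p = 0.892), MYC targets rose in 5 of 21 and fell in 3, also adjusted over the list alone (adjusted p = 0.3). Ribosome biogenesis genes rose in 6 of 52 and fell in 5 (4 and 4 adjusted over the list alone; adjusted p = 0.689), and cytosolic ribosomal protein genes rose in 8 of 79 and fell in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.197). Of 13 replication-dependent histone genes 2 fell (1 adjusted over the list alone; adjusted p = 0.689).

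Markers of other cells were not called either. Of 6 fibroblast markers 2 rose, also adjusted over the list alone (adjusted p = 0.749), with TAGLN, an actin-binding protein that epithelial cells express too, at 0.49, and THY1, a surface protein of fibroblasts, at 1.80, from 0.298 CPM in scramble to 0.302 in C3 and 3.59 in C6. Both calls were lost without scramble replicate 2 (adjusted p = 0.0514 and 0.0569 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 5 leukocyte markers 1 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.969), of 6 endothelial markers 0 rose and 1 fell (1 and 2 adjusted over the list alone; adjusted p = 0.331), and of 6 markers of an embryonic kidney line 1 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.749). The median and the mean fold change of a list differ in sign for ceramidases and sphingosine 1-phosphate genes, lysosomal sphingolipid breakdown, WNT targets, apoptosis regulators, leukocyte markers and endothelial markers, and the test of the colonocyte and fibroblast lists points up where their medians lie below 0.

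Replicates disagreed at a few genes: 19 genes had 0 counts in 1 library of a group and at least 50 in the other. The read-through gene BIVM-ERCC5 had 432 and 0 counts in the C3 libraries and 415 and 0 in the C6 libraries. RPL17-C18orf32 had 143 and 0 in scramble, 0 and 151 in C3, and 183 and 0 in C6. JMJD7-PLA2G4B had 107 and 0 in C3 where PLA2G4B, a gene within it, had 0 and 94.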
